A study of Mus musculus with 24 samples.

How the data were processed

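Polyadenylated RNA from the skin of mouse embryos at embryonic day 15.5 was measured by RNA sequencing in 24 libraries of 4 genotypes. The labels assign 9 libraries to wild type (WT), 5 to an Irf6 knockout (Irf6KO), 5 to Ripk4KD and 5 to a knock-in of Irf6 named Irf6.S413A.S424A, in which the named serines of IRF6 are replaced by alanine. Per the labels' protocols, RNA was purified on columns with DNase digestion, 0.5 ug went into a TruSeq RNA v2 library, and a HiSeq4000 was set to give 30 M single-end reads of 50 bp. That kit does not mark strand, so reads of overlapping genes on opposite strands could not be told apart. Groups were taken from the genotype label alone, and replicate numbers were given in accession order and serve only as names.

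The authors aligned the reads with GSNAP to GRCm38, per the submitters' processing notes; the versions of the aligner and of the annotation are not given in the sources used here. Per the file headers, the deposited counts are reads that aligned uniquely to a gene model, and each library has a value for 36528 gene models identified by Entrez number. The second deposited column is RPKM adjusted by a size factor per library, per the file headers. The 2 columns were checked against each other over 13840 genes: within a gene the RPKM values were proportional to the counts to within 1.24e-14 on the log2 scale, and the size factors behind them lay within 0.0327 log2 units of those computed here. Tests used the counts as deposited, and the RPKM values served only for this check. Symbols came from a RefSeq gene table (31049 gene models) and from GENCODE (77 more), and 5402 models stayed without a symbol; these held 1.24 to 1.56% of the counts of a library and were kept in the tests, but were not named. Positions are those of GRCm38. Reads that aligned to several places had been left out by the authors' counting, so members of near-identical families (Sprr2, Lce, Hba, Hbb, Dsg1) may be undercounted and their single values are uncertain.

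Totals per library were 20.9 to 48.2 M counts. None of the 276 pairs of libraries held identical values. Gene counts were analysed with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr by genotype (19248 of 36528 gene models kept), and the quasi-likelihood F test (glmQLFit, glmQLFTest; two-sided) with Benjamini-Hochberg adjustment at 0.05. All 24 libraries entered 1 fit with a term for genotype and a term for the series of submitter sample numbers. The numbers form 2 series: the first holds 6 WT, 5 Irf6KO and 5 Ripk4KD libraries and the second 3 WT and 5 Irf6.S413A.S424A libraries. A processing batch that followed the numbers would otherwise coincide with the knock-in, and the 9 WT libraries bridge the series. The first series consists of 2 runs of consecutive numbers, with 3 WT libraries each. Standard errors of log2 fold changes were derived from the F statistic. Principal components were computed on the 2000 most variable genes as log2 CPM (counts scaled to library size) with a prior count of 2. Scores of gene lists are the mean log2 CPM of their members.

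The 41 gene lists cover epidermal layers and products, signalling and stress responses, and markers of other cell types of skin. They were tested with camera in limma 3.58.1 (two-sided, preset correlation of 0.01 between genes, lists with at least 3 tested genes) with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated from the data. For each list the members past the threshold were counted in 2 ways, with adjustment over all genes tested and adjusted over the list alone. The design, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined.

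Genes were named by rule. For each genotype against WT these were the 8 largest rises and the 8 largest falls among genes past the threshold with a mean of at least 1 CPM over the 24 libraries and every mutant library outside the range of the 9 WT libraries, and up to 3 members with the smallest adjusted p of each list described. Between genotypes they were the 5 largest in each direction by the same criteria. Irf6 and Ripk4 are always given. Sex-linked, unnamed and predicted genes were left out. Genes given outside this rule are said to be so where they appear and were chosen after their values were seen.

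Where a group held 0 counts of a gene, the fold was computed against a floor of 3 counts over the group and is a lower bound. Where it held 1 to 3 counts, the ratio of count rates in the same number series is given with an exact 95% interval. Without the series term such a ratio was taken against WT of both series. Shares of counts in 1 library carry Wilson 95% intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Other single values were compared with exact permutation tests, two-sided.

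The whole procedure was tested on simulated counts with known changes, drawn from the means and sizes of the real libraries over 18832 genes. For Irf6KO against WT, 39.4% of 1.5-fold, 78.5% of 2-fold and 93.9% of 4-fold changes were recovered, with 9 false calls. For Ripk4KD against WT the shares were 46.2%, 62.7% and 84.8% with 1 false call, for Irf6.S413A.S424A against WT 38.8%, 62.7% and 87.5% with 8, and for Irf6.S413A.S424A against Irf6KO 23.9%, 56.7% and 84.4% with 9. Comparisons that share WT libraries were set beside 20 simulations of unchanged groups against the same WT libraries, and repeated with separate WT libraries per genotype, 3 each.

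Alternatives fixed in advance were no term for the number series, the 3 runs of sample numbers as a block, DESeq2 size factors (RLE) in edgeR, DESeq2 1.42.0, no filter on low counts, fits of only the groups compared, separate WT libraries, an estimated correlation in camera, and each library left out in turn. A term for libraries with Ddx3y above 1 CPM, a covariate for the embryonic share of globin counts, and a fit without Ripk4KD replicate 3, WT replicate 1 and WT replicate 4 were added after seeing the data. The libraries left out were those with the highest granular layer scores. Nothing in the labels says whether libraries of a group came from separate embryos or litters, so p-values measure the spread between these samples, which may in part be technical.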

Results

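Gene expression was measured by RNA sequencing in the skin of mouse embryos of a single labelled stage, when the epidermis is stratifying. IRF6 is a transcription factor needed for keratinocyte differentiation, and RIPK4 is a protein kinase with a role in the same tissue. The 24 libraries comprised 9 of wild type (WT), 5 of an Irf6 knockout (Irf6KO), 5 of Ripk4KD and 5 of the knock-in Irf6.S413A.S424A. The title of the series calls the Ripk4 allele KD, its design text calls it a knockout, and the source label uses the words kinase dead for all samples, so the name is used here without expanding it. Depth was 20.9 to 48.2 M counts per library with a median of 35.9 M. In each library 22400 to 24947 genes had at least 1 count. WT libraries held 23.3 to 48.2 M counts, Irf6KO 32.7 to 46.5, Ripk4KD 30.8 to 42.0 and Irf6.S413A.S424A 20.9 to 26.2. In the text, SE is the standard error on the log2 scale, adjusted p values of genes come from edgeR and those of gene lists from limma camera.

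Irf6 (gene 54139, GRCm38 chromosome 1, 193153112 to 193172036) stood at 151 ± 16.2 CPM (SD, n = 6) in the WT libraries of the first number series and at 29.4 ± 4.95 (n = 5) in Irf6KO. It was 5.16-fold lower (log2 -2.37, SE 0.19, adjusted p = 7.96e-09), and the 5 Irf6KO libraries (22.1 to 34.3 CPM) lay below all 9 WT libraries (131 to 248). The knock-in leaves the transcript in place: Irf6 was at 247 ± 37.2 CPM (n = 5) in Irf6.S413A.S424A and 241 ± 9.91 (n = 3) in the WT libraries of the second series (log2 0.04, SE 0.21, adjusted p = 0.945). In Ripk4KD Irf6 was at 122 ± 49.6 CPM (n = 5; log2 -0.31, SE 0.18, adjusted p = 0.418), with the highest value, 195 CPM, in Ripk4KD replicate 3. Leaving out that library gave a difference of -0.54 (adjusted p = 0.027).

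Ripk4 (gene 72388, chromosome 16, 97741933 to 97763779) was at 68.2 ± 10.7 CPM (n = 6) in first-series WT and 80.8 ± 22.8 (n = 5) in Ripk4KD (log2 0.24, SE 0.17, adjusted p = 0.508), so the gene's count did not check the Ripk4KD label. In Irf6KO it was at 88.7 ± 21.7 CPM (log2 0.38, SE 0.17, adjusted p = 0.133). Irf6KO replicate 5 held 51 CPM and the others 91.5 to 104. Without it the difference was 0.52 (adjusted p = 0.0142). Ripk4 was 1.55-fold higher in Irf6.S413A.S424A, at 120 ± 12.5 CPM (n = 5) against 77.2 ± 5.25 (n = 3; SE 0.21, adjusted p = 0.0387). That call was lost without WT replicate 3, 5 or 9 (adjusted p = 0.0959, 0.151 and 0.102) and without Irf6.S413A.S424A replicate 3, 4 or 5 (0.0629, 0.0622 and 0.0879).

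**Figure D1:**
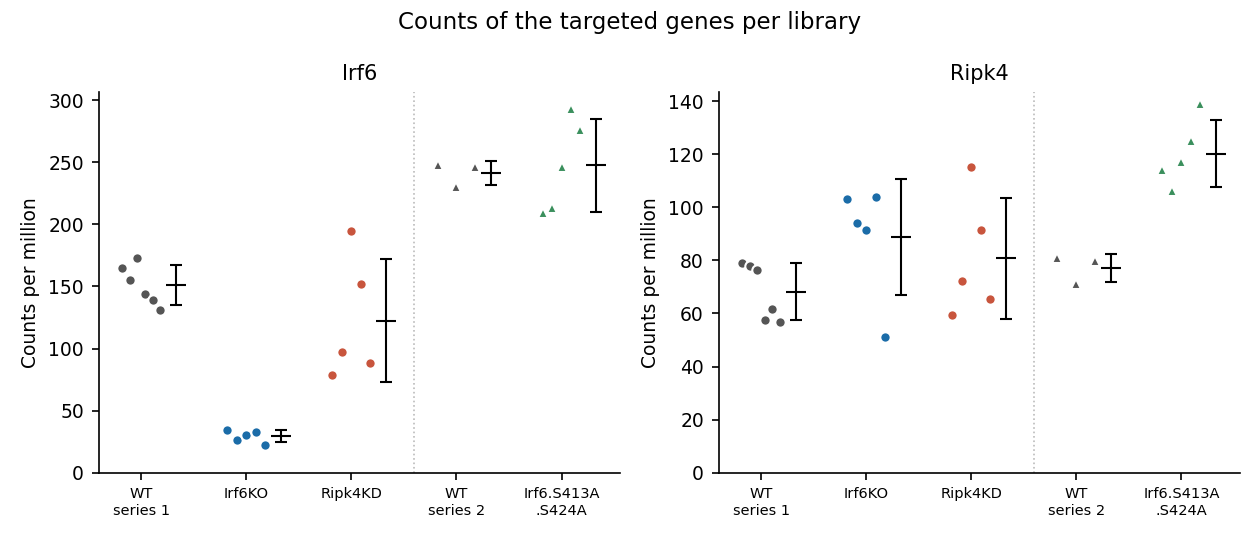
CPM (counts scaled to library size) of Irf6 and Ripk4 in each of the 24 libraries, with bars for mean and SD per group and the 2 sample number series on either side of the dotted line. The 5 Irf6KO libraries lie between 22.1 and 34.3 CPM of Irf6, below all WT libraries, and Ripk4 is not lower in Ripk4KD.

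On the first principal component (49.9% of variance) the WT libraries lay at -73.4 to -32.2, Irf6KO at 37.2 to 43.3 and Irf6.S413A.S424A at 45.8 to 52.7. Ripk4KD lay between at 0.8 to 17.4, except replicate 3 at -35.5. On the second component (16.6%) the libraries of the second number series lay at -38.5 to -27.2 and those of the first at -12.7 to 36.7. Between WT libraries of the second and first series, 6096 of 18684 genes differed (2891 higher, 3205 lower; 3 against 6 libraries). Between the WT libraries of the 2 runs within the first series, edgeR called 0 of 18537 genes (3 against 3 libraries; 203 at unadjusted p under 0.05).

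**Figure D2:**
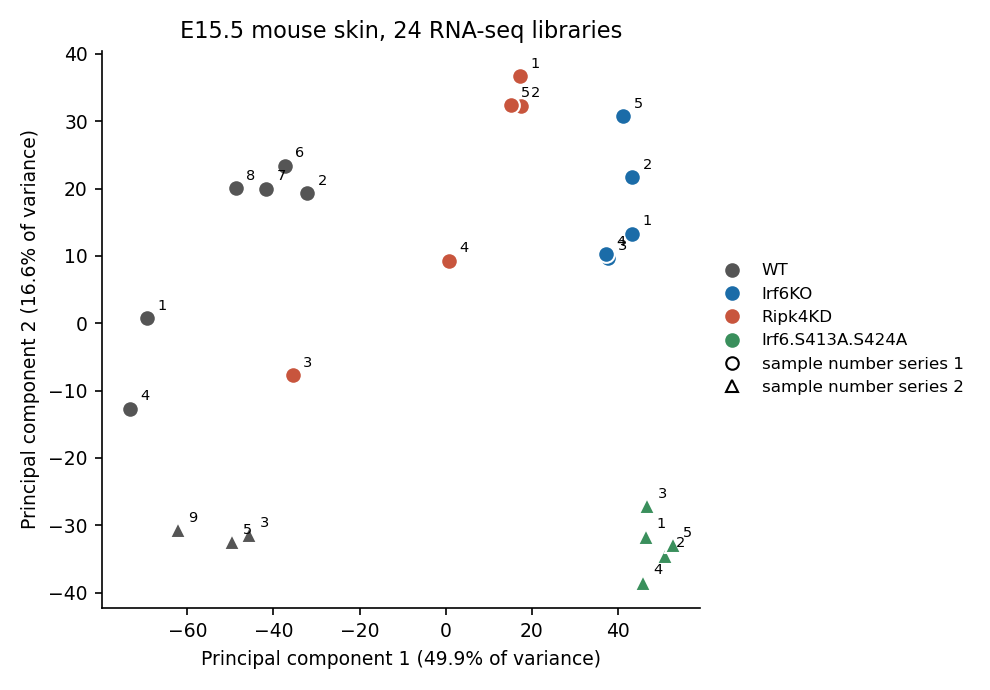
Principal components 1 and 2 of log2 CPM over the 2000 most variable genes, with replicate numbers, colours for genotype and shapes for sample number series. Ripk4KD replicate 3 lies at -35.5 on component 1, among the WT libraries and away from the other 4 Ripk4KD libraries.

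Ripk4KD replicate 3 also stood apart in keratinocyte genes. Its granular and cornified layer score was 6.93 log2 CPM, against 2.06 to 3.62 in the other 4 Ripk4KD libraries and 4.42 to 7.46 in WT. Embryonic globins (Hbb-y, Hbb-bh1 and Hba-x), which give way to adult globins as development proceeds, made up 0.29% of its globin counts (Wilson 95% interval 0.254 to 0.332), against 2.65 to 5.34% in the others. The share was also low in WT replicate 1 (0.533%, 0.478 to 0.594), WT replicate 4 (0.496%, 0.448 to 0.549) and Irf6KO replicate 4 (0.966%, 0.879 to 1.06), and 1.42 to 6% in the other WT libraries. WT replicates 4 and 1 had the highest granular scores of WT, 7.46 and 7.09.

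**Figure D3:**
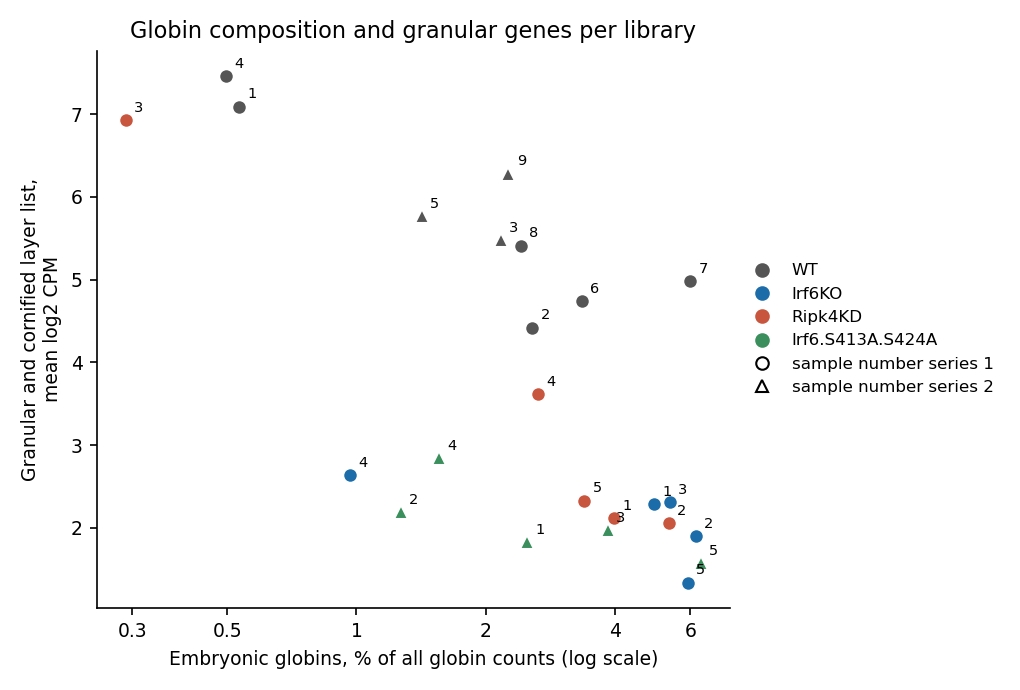
Embryonic share of globin counts (log axis, percent) against the granular and cornified layer score (mean log2 CPM) in each library. Ripk4KD replicate 3 lies at 0.29% and 6.93, next to WT replicates 1 and 4.

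Irf6KO was set against WT to ask what the loss of Irf6 changes in embryonic skin. Most spinous and granular layer genes fell, by very different amounts. Krt77, a suprabasal keratin, fell from 1940 ± 576 CPM (SD, n = 9) to 2.93 ± 0.825 (n = 5), and Acer1, an alkaline ceramidase of differentiated keratinocytes, from 95.1 ± 30.5 to 0.135 ± 0.0265. Lor, which encodes the cornified envelope protein loricrin and was chosen after its values were seen, fell from 2720 ± 2110 to 6.49 ± 1.46 CPM. Il24, a cytokine of the IL-10 family, rose from 0.0151 ± 0.0194 to 9.2 ± 4.64 CPM, and Epgn, a ligand of the EGF receptor, from 1.23 ± 0.328 to 49.1 ± 20.8. In all, 3209 of 19248 genes (16.7%) passed the threshold, 1262 higher and 1947 lower, of which 278 and 883 changed at least 2-fold. With the 3 runs of sample numbers as a block the count was 1883.

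The largest rises by the naming rule were Il24 (456-fold, SE 0.83, adjusted p = 7.47e-08), the near-identical family member Sprr2a3 (161-fold, SE 0.68), Csta3 (95.7-fold, SE 0.98), Krt16 (71.4-fold, SE 1.15, adjusted p = 0.000497), Krt75 (59.5-fold, SE 0.47), Krt6b (53.7-fold, SE 1.55, adjusted p = 0.0113), Epgn (44-fold, SE 0.46) and C2cd4b (40.2-fold, SE 0.74). Krt6b did not pass with the 3 runs as a block (adjusted p = 0.0992). The log2 rise of Krt16 was 5.46 and that of Krt6b 4.47 without Irf6KO replicate 4, that of Krt75 was 6.61 without WT replicate 4, and that of C2cd4b was 5.93 without WT replicate 7. The largest falls were those of Il1f6 and P2ry4, with 0 counts in all 5 Irf6KO libraries (at least 330-fold and at least 209-fold lower, but at least 96.1-fold and at least 82.1-fold without WT replicate 4, and at least 22.3-fold and at least 56.9-fold without Ripk4KD replicate 3, WT replicate 1 and WT replicate 4), Hrnr (690-fold lower, SE 1.59), Krt77 (680-fold, SE 0.7, adjusted p = 2.63e-09), Acer1 (661-fold, SE 1.07), Slc34a2 (650-fold, SE 1.92), Lypd5 (599-fold, SE 1.6) and Psca (589-fold, SE 1.04). Without WT replicate 4 the log2 changes of Hrnr and Slc34a2 were -8.82 and -8.46, and without Irf6KO replicate 3 that of Slc34a2 was -10.14. With the embryonic globin share in the fit the rises were larger for Krt6b (249-fold), Csta3 (234-fold), Krt16 (135-fold), Sprr2a3 (271-fold) and Il24 (699-fold), and the falls were smaller: Hrnr was 118-fold, Slc34a2 244-fold, Psca 280-fold, Lypd5 309-fold, Acer1 391-fold and Krt77 437-fold lower. Leaving out Ripk4KD replicate 3, WT replicate 1 and WT replicate 4 gave falls of 191-fold for Hrnr, 228-fold for Slc34a2, 272-fold for Psca and 365-fold for Lypd5, and rises of 114-fold for Krt75 and 128-fold for Krt6b. A sex term moved values the other way, to rises of 41.6-fold for Krt16 and 26.2-fold for Krt6b and falls of 1640-fold for Slc34a2, 1580-fold for Lypd5, 1120-fold for Hrnr and 1040-fold for Acer1.

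Most suprabasal and basal genes moved in opposite directions. Of 17 spinous layer genes 16 fell, also adjusted over the list alone, among them Skint6 (60.7-fold, SE 0.69; 36-fold with the embryonic globin share) and Krt2, whose 3 counts in Irf6KO put it 39.4-fold lower (counting interval 13.2 to 193); the list's adjusted p was 4.37e-16, and adjusted p = 0.119 with an estimated correlation. Of 20 granular and cornified layer genes 15 fell and 19 fell adjusted over the list alone, among them Scel (17.4-fold, SE 0.46) and the envelope protein gene Evpl (8.02-fold, SE 0.4). Adjusted p for this list was 1.49e-12 with the preset and adjusted p = 0.203 with an estimated correlation. Of 17 basal keratinocyte genes 10 rose and 1, Krt15, fell, the same counts as adjusted over the list alone. Lamc2, a laminin chain, rose 4.2-fold (SE 0.23), the integrin gene Itgb4 2.44-fold (SE 0.16) and Cdh3 1.99-fold (SE 0.12). Its list had adjusted p = 3.24e-07 with the preset and adjusted p = 0.203 with an estimated correlation. Of the layer keratins chosen after their values were seen, Krt5 rose 2.79-fold (SE 0.23) and Krt14 4.01-fold (SE 0.35), and Krt10 fell 10.4-fold (SE 0.62) and Krt1 3.87-fold (SE 0.57). The basal score was 7.63 in Irf6KO replicate 5, inside the 7.26 to 7.91 of first-series WT, and 8.17 to 8.36 in the other 4. The granular score was lowest in replicate 5 (1.34) and highest in replicate 4 (2.64), which had the low embryonic globin share.

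Barrier lipid genes fell in 22 of 28 cases (24 lower and 1 higher adjusted over the list alone), among them Dgat2 (16.1-fold, SE 0.43; 10.4-fold with the embryonic globin share) and the acylceramide gene Pnpla1 (9.75-fold, SE 0.38). The list's adjusted p was 8.3e-20 with the preset and adjusted p = 0.1 with an estimated correlation. Cholesterol synthesis genes fell by less, 16 of 24 (19 adjusted over the list alone), with Mvk 1.72-fold (SE 0.14) and Dhcr24 1.77-fold lower (SE 0.15). For the list, adjusted p was 1.53e-10 with the preset and adjusted p = 0.148 with an estimated correlation. Of 19 fatty acid genes 9 fell by both counts (9 adjusted over the list alone), with Acsl1 6.23-fold (SE 0.38) and Me1 2.67-fold lower (SE 0.2). As a list it had adjusted p = 4.89e-05 with the preset and adjusted p = 0.0674 with an estimated correlation.

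Tight junction genes fell in 11 of 20 cases and 1, Cldn6, rose (12 and 1 adjusted over the list alone): the claudin Cldn23 was 154-fold (SE 0.31), Cldn3 14-fold (SE 0.33) and Ocln 12.1-fold lower (SE 0.23). The periderm, a transient outer cell layer, shares its list with simple keratins: 10 of 13 genes fell (10 adjusted over the list alone), with Krt4 311-fold (SE 0.43), Upk1b 44.8-fold (SE 0.24) and Krt19 38.3-fold lower (SE 0.24), whereas Krt17 and Krt6b, keratins that also mark stressed epidermis, rose. Both held with an estimated correlation (adjusted p = 0.00119 each). Krt4 and Krt13 (122-fold lower, SE 0.85; 56.1-fold with the embryonic globin share) also accounted for 2 of the 4 falls among 7 oral and oesophageal genes (1 rose; 6 lower and 1 higher adjusted over the list alone; adjusted p = 0.00224 with an estimated correlation). Of 33 epidermal transcription factor genes 17 fell and 4 rose (19 and 4 adjusted over the list alone), with Elf5 69.7-fold (SE 0.37) and Grhl3 5.05-fold lower (SE 0.26). This list's adjusted p was 8.92e-08 with the preset and adjusted p = 0.358 with an estimated correlation. Protease and inhibitor genes fell in 8 of 23 cases (11 adjusted over the list alone), among them Spink5 (132-fold, SE 1.32), at log2 -6.18 without WT replicate 4 and 33.8-fold lower with the share (list adjusted p = 0.000417, adjusted p = 0.509 with an estimated correlation).

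Stress keratins and alarmins split: 9 of 17 rose and 5 fell (11 and 5 adjusted over the list alone). Krt17 rose 9.52-fold (SE 0.22) and Il1b 16.3-fold (SE 0.54), the latter at log2 3.38 without Irf6KO replicate 1, whereas Il1f5 and Il1f6, which encode the IL-36 receptor antagonist and an IL-36 cytokine, fell. Il1f5 was 69.4-fold lower (SE 0.88), and 29.9-fold with the embryonic globin share in the fit. The list's adjusted p was 0.00112, and adjusted p = 0.509 with an estimated correlation. In the Sprr family 6 of 11 genes rose and 2 fell (7 and 2 adjusted over the list alone): Sprr2 members rose and Sprr3 was 531-fold lower (SE 1.12), at log2 -8.40 without WT replicate 1 and 221-fold lower with the share (list adjusted p = 0.00171, adjusted p = 0.47 with an estimated correlation).

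Inflammatory genes rose together. Of 20 NF-kB and inflammatory genes 14 rose and 0 fell (15 and 0 adjusted over the list alone), with Bcl3 6.54-fold (SE 0.22), the chemokine Cxcl10 6.13-fold (SE 0.24) and Icam1 2.21-fold higher (SE 0.09). Adjusted p for this list was 1.94e-15 with the preset and adjusted p = 0.000583 with an estimated correlation. Of 25 interferon response genes 14 rose (16 adjusted over the list alone), with Oasl2 3.98-fold (SE 0.21), Gbp2 3.49-fold (SE 0.23) and Usp18 3.24-fold higher (SE 0.22). Its list had adjusted p = 4.8e-13 with the preset and adjusted p = 0.0264 with an estimated correlation. Macrophage and leukocyte genes rose with them in 4 of 19 cases (8 adjusted over the list alone), among them Cd14 (1.93-fold, SE 0.17). The list's adjusted p was 0.00035 with the preset and adjusted p = 0.419 with an estimated correlation. The leukocyte score was 0.32 log2 units above first-series WT (exact permutation p = 0.00433, 5 of 5 libraries above all 6 WT) and the interferon score 0.80 above it (p = 0.00216, the smallest this exact test can give). Immediate early genes rose in 8 of 19 cases and fell in 1 (9 and 2 adjusted over the list alone), with Ccn2 4.16-fold (SE 0.2) and Egr1 1.99-fold higher (SE 0.17). For the list, adjusted p was 0.000357 with the preset and adjusted p = 0.148 with an estimated correlation.

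In the pericyte and smooth muscle list 5 of 12 genes rose (5 adjusted over the list alone) while the median log2 change was 0: those that rose were genes of the contractile apparatus, among them Tagln (14.4-fold, SE 0.24), Acta2 (5.41-fold, SE 0.17) and Myh11 (3.68-fold, SE 0.28), and Mcam. As a list it had adjusted p = 5.75e-06 with the preset and adjusted p = 0.0121 with an estimated correlation. Skeletal muscle genes fell in 14 of 25 cases (22 adjusted over the list alone), for example Ckm 2.09-fold (SE 0.24) and Casq2 1.58-fold (SE 0.15). This list's adjusted p was 1.33e-08 with the preset and adjusted p = 0.251 with an estimated correlation. Melanocyte genes rose in 3 of 11 cases (5 adjusted over the list alone), with Gpnmb 2.66-fold higher (SE 0.17). Adjusted p for this list was 0.000182 with the preset and adjusted p = 0.251 with an estimated correlation. Of 26 S phase genes 6 rose (10 adjusted over the list alone), with a median log2 change of 0.21 (list adjusted p = 0.000114, adjusted p = 0.509 with an estimated correlation). The erythroid list was lower (median -0.35, 2 of 18 genes lower, 2 adjusted over the list alone; adjusted p = 0.00875, adjusted p = 0.509 with an estimated correlation), a call lost without WT replicate 6 (0.0659). The fibroblast, endothelium, mast cell and Schwann cell lists did not pass (adjusted p = 0.819 for fibroblasts and 0.767 for endothelium). Nor did the desmosome, placode, Notch and hypoxia lists (adjusted p = 0.908, 0.767, 0.767 and 0.261).

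**Figure D4:**
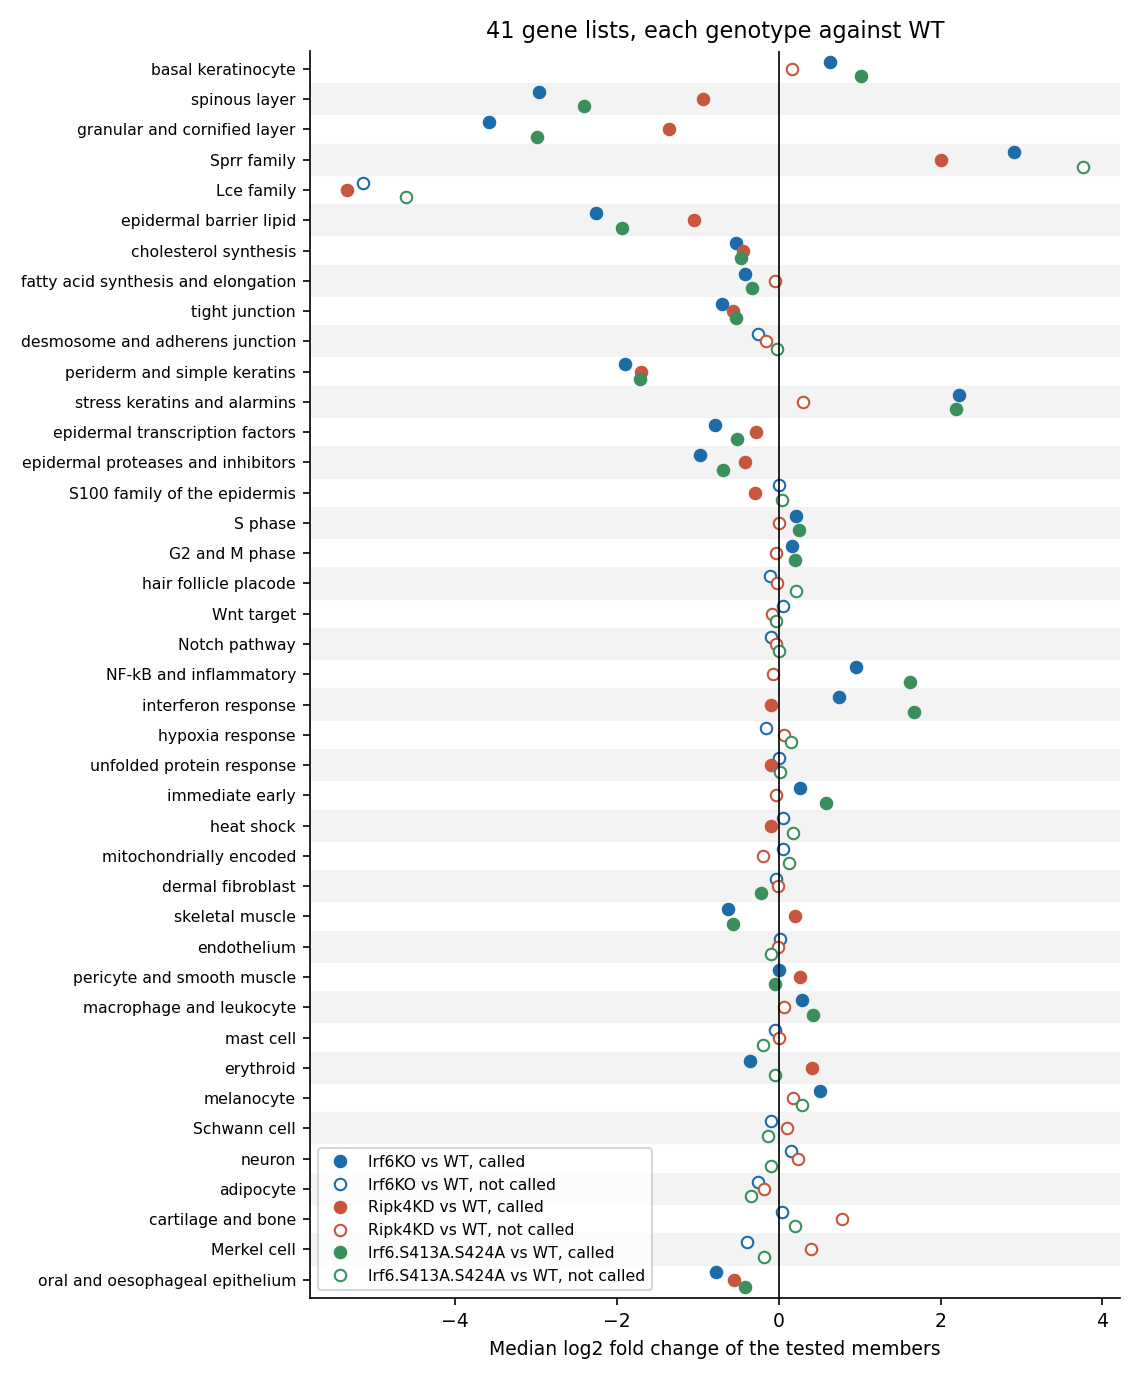
Median log2 fold change of the tested members of each of the 41 gene lists in each genotype against WT, filled where the list passed adjusted p 0.05 in camera with the preset correlation. Suprabasal, barrier lipid, tight junction and periderm lists lie below 0 in all 3 genotypes, and the NF-kB and interferon lists lie above 0 only in Irf6KO and Irf6.S413A.S424A.

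Ripk4KD was set against WT to ask what the Ripk4 allele changes. Periderm and tight junction genes fell, and Krt17 and Epgn were among the 85 genes that rose. Cldn23, a claudin, fell from 40.1 ± 11.8 CPM (SD, n = 9) to 1.15 ± 0.679 (n = 5), Krt4 from 718 ± 237 to 63.1 ± 24.4, and Elf5, an epithelial transcription factor, from 44.7 ± 15.9 to 1.64 ± 0.488. Krt17 rose from 143 ± 32.7 to 582 ± 186 CPM and Epgn from 1.23 ± 0.328 to 29.2 ± 20.4. In all, 653 of 19248 genes (3.4%) passed, 85 higher and 568 lower, of which 36 and 312 changed at least 2-fold. The count depended on single libraries: it was 1739 without Ripk4KD replicate 3, the library with the granular score near WT, 399, 406 and 426 without Ripk4KD replicates 2, 5 and 1, and 404 without WT replicate 1. It was 297 with the 3 runs as a block and 349 with only the groups compared in the fit.

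The largest rises were Sprr2a3 (31.1-fold, SE 0.66), Epgn (26.2-fold, SE 0.45, adjusted p = 6.49e-07), Krt75 (21.2-fold, SE 0.45), Htr1d (12.1-fold, SE 0.38, adjusted p = 2.67e-06), the cytokine Tslp (10.9-fold, SE 0.65), Adgrg7 (4.78-fold, SE 0.38), Krt17 (3.98-fold, SE 0.21, adjusted p = 2.35e-06) and the oxidase Duox1 (3-fold, SE 0.31). Without Ripk4KD replicate 3 the log2 rises of Sprr2a3 and Tslp were 3.57 and 1.90, and without WT replicate 4 that of Krt75 was 5.12. The largest falls were Krtap13 (4000-fold, SE 2.08, from 171 ± 300 CPM in WT), Il1f6 with 2 counts in Ripk4KD (ratio 439, counting interval 121 to 3630), Lce3f (212-fold, SE 1.06), Dynap (62.8-fold, SE 1), Sprr3 (52.7-fold, SE 0.87), Lce6a (40.3-fold, SE 0.82), Psca (39.2-fold, SE 0.79) and Prr9 (38.8-fold, SE 0.59, adjusted p = 5.04e-06). Without Ripk4KD replicate 3 the log2 changes were -8.57 for Dynap, -11.06 for Lce3f, -6.50 for Lce6a, -6.86 for Sprr3 and -6.42 for Psca. Without WT replicate 4 they were -10.91 for Krtap13, -7.05 for Lce3f and -4.73 for Lce6a, without WT replicate 1 -5.06 for Sprr3, and without Ripk4KD replicate 1 -13.18 for Krtap13. Krtap13 was 169-fold lower without Ripk4KD replicate 3, WT replicate 1 and WT replicate 4 together. Il1f6 (adjusted p = 0.0215) lost its call without Ripk4KD replicate 1, 2, 4 or 5 (0.0649, 0.0706, 0.0673 and 0.0693). Its ratio was 128 (35.1 to 1060) without WT replicate 4, 48.8 (8.4 to 1970) without those 3 libraries, and 677 (121 to 26800) and 720 (129 to 28500) without Ripk4KD replicates 1 and 3.

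Suprabasal genes fell in fewer cases than the number tested, and Ripk4KD replicate 3 set how many. Of 17 spinous genes 4 fell (8 adjusted over the list alone), among them Krt77 (8.41-fold, adjusted p = 0.000734) and Krt2 (4.15-fold, SE 0.39), and without replicate 3 there were 15 (15 adjusted over the list alone), with Krt77 at log2 -4.24 (list adjusted p = 8.22e-11, adjusted p = 0.346 with an estimated correlation). Of 20 granular genes 6 fell (10 adjusted over the list alone), among them Scel (4.28-fold, SE 0.41), and without replicate 3 there were 18, with Scel at log2 -2.96 (list adjusted p = 4.96e-10, adjusted p = 0.369 with an estimated correlation). Among markers chosen after their values were seen, Lor differed by log2 -3.30 (SE 1.16, adjusted p = 0.138), with 1560 CPM in replicate 3, 4.02 to 10.8 in the other 4 and 1040 to 6810 in WT; without replicate 3 it was 448-fold lower (SE 0.63, adjusted p = 3.83e-09). Krt10 differed by log2 -0.45 (adjusted p = 0.736), and without replicate 3 was 3.03-fold lower (SE 0.46, adjusted p = 0.0321). Basal genes did not rise: 0 of 17 were higher (0 adjusted over the list alone) and 1, Krt15, was 1.62-fold lower (SE 0.13; list adjusted p = 0.733, with 0 higher and 2 lower without replicate 3). Krt5 and Krt14 differed by log2 0.21 and 0.56 (adjusted p = 0.686 and 0.447).

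Barrier lipid genes fell in 7 of 28 cases (21 lower and 1 higher adjusted over the list alone; 24 lower without replicate 3), among them Lipk (11.6-fold, SE 0.67) and Dgat2 (3.53-fold, SE 0.38), at log2 -4.76 and -2.57 without replicate 3 (list adjusted p = 3.91e-16, adjusted p = 0.206 with an estimated correlation). Dgat2 did not pass with only the groups compared in the fit (adjusted p = 0.0765). Cholesterol synthesis genes fell in 6 of 24 cases (16 adjusted over the list alone; 16 over all genes without replicate 3), among them Fdps (1.87-fold, SE 0.16) and Pmvk (1.62-fold, SE 0.13). Its list had adjusted p = 4.62e-15 with the preset and adjusted p = 0.107 with an estimated correlation. The fatty acid list did not pass (0 of 19 genes lower, 0 adjusted over the list alone; adjusted p = 0.313).

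Tight junction genes fell in 9 of 20 cases (11 adjusted over the list alone; 12 without replicate 3), with Cldn23 30.8-fold (SE 0.27), Ocln 4.22-fold (SE 0.21) and Cldn4 3.39-fold lower (adjusted p = 3.91e-16, adjusted p = 0.0034 with an estimated correlation). Periderm and simple keratin genes fell in 7 of 13 cases and rose in 3 (7 and 4 adjusted over the list alone; 7 and 2 without replicate 3): Krt4 was 10.4-fold (SE 0.33), Upk1b 5.33-fold (SE 0.2) and Krt19 4.23-fold lower (SE 0.2), and Krt17 rose (adjusted p = 1.42e-10, adjusted p = 0.0221 with an estimated correlation). Of 33 transcription factor genes 7 fell (11 lower and 1 higher adjusted over the list alone; 16 lower without replicate 3), with Elf5 22.7-fold (SE 0.34), Hopx 7.8-fold (SE 0.46; log2 -3.77 without replicate 3) and Grhl3 2.33-fold lower (SE 0.24). The list's adjusted p was 3.14e-08 with the preset and adjusted p = 0.403 with an estimated correlation. Protease and inhibitor genes fell in 6 of 23 cases (6 adjusted over the list alone; 15 without replicate 3), among them the protease inhibitor Spint1 (2.38-fold, SE 0.22) and its target protease St14 (1.82-fold, SE 0.16). For the list, adjusted p was 7.83e-07 with the preset and adjusted p = 0.403 with an estimated correlation.

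The rise of inflammatory genes seen in Irf6KO was not found. Of 20 NF-kB and inflammatory genes only Tslp was higher over all genes (3 higher and 1 lower adjusted over the list alone; list adjusted p = 0.885), and Icam1 and Cxcl10, chosen here after their values were seen, differed by log2 -0.06 (SE 0.09) and 0.37 (SE 0.25). The interferon list was lower by a median of -0.10 with 0 genes higher and 1 lower (0 and 1 adjusted over the list alone; adjusted p = 0.00479, adjusted p = 0.439 with an estimated correlation), a call that ended with the 3 runs as a block (0.162) and without the series term (0.153). The leukocyte score differed by 0.06 log2 units (exact permutation p = 0.667, n = 5 and 6). Tagln rose 2.23-fold (SE 0.22) and Acta2 1.99-fold (SE 0.16), 2 of 12 genes of the pericyte and smooth muscle list (4 adjusted over the list alone). As a list it had adjusted p = 0.000108 with the preset and adjusted p = 0.0335 with an estimated correlation. Skeletal muscle genes, which fell in Irf6KO, were higher as a list (median 0.20, 0 of 25 genes past the threshold, 0 adjusted over the list alone; adjusted p = 0.00479, adjusted p = 0.651 with an estimated correlation), a call lost without WT replicate 4 (0.0828). The erythroid list was higher too (median 0.41, 0 of 18 genes higher and 1 lower, 0 and 1 adjusted over the list alone; adjusted p = 0.00983, adjusted p = 0.601 with an estimated correlation), and was lost without WT replicate 4 or Ripk4KD replicate 1 (0.102 and 0.234). Among stress keratins and alarmins 3 of 17 rose and 4 fell (7 and 5 adjusted over the list alone), with a median of 0.30 and a test in the other direction (adjusted p = 0.954). Krt16 rose 51.2-fold (adjusted p = 0.0038) with 1010 CPM in replicate 3 and 5.92 to 63.6 in the others; without replicate 3 it was 5.22-fold higher (SE 0.7, adjusted p = 0.0331), and with the 3 runs as a block it did not pass (0.0785).

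Irf6.S413A.S424A was set against WT to ask what the knock-in changes at the usual Irf6 RNA level. Protein was not measured. Krt77 stood at 1.45 ± 0.722 CPM (SD, n = 5) against 1940 ± 576 in WT (n = 9), Krt4 at 1.37 ± 0.629 against 718 ± 237, and Upk1b, a periderm uroplakin, at 1.95 ± 0.468 against 178 ± 67.7. Il24 rose to 16.7 ± 6.19 CPM, Krt17 to 1710 ± 264 against 143 ± 32.7, and Oasl2, an interferon-induced gene, to 19.9 ± 3.23 against 2.62 ± 0.821. In all, 2934 of 19248 genes (15.2%) passed, 1504 higher and 1430 lower, of which 489 and 741 changed at least 2-fold. The contrast rests on the 3 WT libraries of its own series: without WT replicate 9 the count was 1872, and without the series term it was 7802.

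The largest rises were Il24 (1 count in second-series WT, ratio 1180, counting interval 211 to 46400), C2cd4b and Lce3c with 0 counts there (at least 72.6-fold and at least 67.5-fold), the collagenase Mmp13 (ratio 381, 68.2 to 15100), Sprr2a3 (187-fold, SE 0.95), Krt16 (128-fold, SE 1.67, adjusted p = 0.00497), the serotonin receptor gene Htr1d (104-fold, SE 0.59, adjusted p = 3.21e-08) and Csta3 (77.1-fold, SE 1.29). Without WT replicate 3 the log2 rise of Htr1d was 8.22, the ratio of Il24 766 (137 to 30300), and C2cd4b, Lce3c and Mmp13 were at least 47.3-fold, 43.9-fold and 82.8-fold higher, and without WT replicate 5 Il24 was at least 264-fold higher. Without the series term, against WT of both series, the ratio was 16.3 (12.2 to 22) for Lce3c, 60.1 (36.5 to 106) for C2cd4b and 120 (71.2 to 221) for Mmp13. Without Irf6.S413A.S424A replicate 4 the ratio of Mmp13 was 209 (37.1 to 8270) and the log2 rises of Krt16 and Csta3 were 6.41 and 5.59. Psca and Slc46a2 had 0 counts in all 5 libraries (at least 2540-fold and at least 869-fold lower). Sdr9c7, a gene of barrier lipid synthesis, had 1 count (ratio 7850, counting interval 1410 to 310000), and Krtap13 and Sprr3 had 2 each (2950, 815 to 24300, and 2440, 674 to 20100). Without WT replicate 9 these 2 ratios were 1760 (485 to 14500) and 1580 (437 to 13100), and without the series term that of Krtap13 was 11500 (3170 to 94600). Without Irf6.S413A.S424A replicate 1 Sdr9c7 and Krtap13, and without replicate 3 Sprr3, had 0 counts (at least 2070-fold, 1550-fold and 1340-fold lower). Hrnr (1290-fold, SE 1.74), Cnfn (1260-fold, SE 1.57) and Krt77 (1250-fold, SE 0.76, adjusted p = 2.89e-09) followed.

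Of 17 spinous genes 13 fell (15 lower and 1 higher adjusted over the list alone), with Skint6 61.2-fold lower (SE 0.72) and Krt2 at 3 counts (ratio 21.5, 6.81 to 109). This list's adjusted p was 6.29e-14 with the preset and adjusted p = 0.137 with an estimated correlation. Of 20 granular genes 11 fell (12 adjusted over the list alone), among them Scel (20.3-fold, SE 0.49) and Evpl (7.53-fold, SE 0.44). Adjusted p for this list was 1.29e-11 with the preset and adjusted p = 0.235 with an estimated correlation. Of 17 basal genes 11 rose and Krt15 fell (12 and 1 adjusted over the list alone), with Lamc2 7.91-fold (SE 0.31), Itgb4 3.41-fold (SE 0.2) and Cdh3 2.42-fold higher (SE 0.15). Its list had adjusted p = 1.07e-10 with the preset and adjusted p = 0.108 with an estimated correlation. The dermal fibroblast list was lower (median -0.22, 2 of 24 genes lower, 2 adjusted over the list alone; adjusted p = 0.0157, adjusted p = 0.696 with an estimated correlation), but not without WT replicate 5 (0.0881), Irf6.S413A.S424A replicate 5 (0.0676) or Ripk4KD replicate 3, WT replicate 1 and WT replicate 4 together (0.0808). Among keratins chosen after their values were seen, Krt5 rose 3.35-fold (SE 0.29) and Krt14 4.89-fold (SE 0.46), Krt10 fell 6.58-fold (SE 0.66), and Krt1 differed by log2 -1.29 (adjusted p = 0.201). Embryonic globin shares were 1.27 to 6.36% in these 5 libraries and 1.42 to 2.26% in second-series WT.

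Barrier lipid genes fell in 18 of 28 cases (23 lower and 1 higher adjusted over the list alone), among them Dgat2 (14.7-fold, SE 0.46) and Lipm (22.6-fold, SE 0.6). Adjusted p of the list was 4.52e-18 with the preset and adjusted p = 0.108 with an estimated correlation. Cholesterol genes fell in 14 of 24 (15 adjusted over the list alone), with Mvk 1.73-fold and Pmvk 1.69-fold lower (adjusted p = 3.67e-08, adjusted p = 0.225 with an estimated correlation). Fatty acid genes fell in 7 of 19 (10 adjusted over the list alone), with Acsl1 6.93-fold and Me1 2.99-fold lower (adjusted p = 0.000151, adjusted p = 0.0867 with an estimated correlation). Tight junction genes fell in 9 of 20 and Cldn6 rose (11 and 1 adjusted over the list alone), with Cldn23 197-fold (SE 0.34) and Ocln 10-fold lower (SE 0.24), and periderm genes fell in 9 of 13 and Krt17 rose (10 and 3 adjusted over the list alone), with Krt4 610-fold (SE 0.46) and Upk1b 124-fold lower (SE 0.27). Both held with an estimated correlation (adjusted p = 0.00414 and 0.00138). Of 33 transcription factor genes 12 fell and 3 rose (12 and 5 adjusted over the list alone), with Elf5 118-fold lower (SE 0.41). For the list, adjusted p was 0.000601 with the preset and adjusted p = 0.696 with an estimated correlation.

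Of 25 interferon response genes 20 rose (20 adjusted over the list alone), with Oasl2 10.3-fold (SE 0.29), Gbp2 8.92-fold (SE 0.33) and Irf9 2.04-fold higher (SE 0.09). As a list it had adjusted p = 9.94e-27 with the preset and adjusted p = 0.00178 with an estimated correlation. Of 20 NF-kB and inflammatory genes 15 rose (16 adjusted over the list alone), with Cxcl10 12.9-fold (SE 0.34), Bcl3 9.68-fold (SE 0.31) and Icam1 2.88-fold higher (SE 0.11). This list's adjusted p was 1.86e-18 with the preset and adjusted p = 0.000214 with an estimated correlation. Leukocyte genes rose beside them in 6 of 19 cases (8 adjusted over the list alone), with Cd14 3.62-fold (SE 0.23) and Lyz2 2.44-fold higher (list adjusted p = 0.000748, adjusted p = 0.514 with an estimated correlation). The leukocyte score was 0.40 and the interferon score 1.62 log2 units above WT of the series, each with exact permutation p = 0.0179, the smallest that 5 against 3 libraries allow. Immediate early genes rose in 10 of 19 cases (12 adjusted over the list alone), among them Ccn2 (7.09-fold, SE 0.27), Ccn1 (3.4-fold, SE 0.23) and Jun (2.09-fold, SE 0.12). Adjusted p for this list was 1.23e-08 with the preset and adjusted p = 0.0128 with an estimated correlation. The stress keratin and alarmin list rose (8 of 17 higher, 4 lower; 10 and 4 adjusted over the list alone; adjusted p = 0.038, adjusted p = 0.696 with an estimated correlation), with Krt17 12.5-fold higher (SE 0.3) and S100a7a 16.4-fold lower (SE 0.6). That call was lost without WT replicate 3, 4 or 5 (adjusted p = 0.121, 0.081 and 0.0664), and without WT replicate 9 S100a7a stood at log2 -3.45.

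In the pericyte and smooth muscle list Tagln rose 23.1-fold (SE 0.34), Acta2 7.84-fold (SE 0.23) and Mcam 1.54-fold (SE 0.08); 5 of 12 genes rose (5 adjusted over the list alone) although the median was -0.05, opposite in sign to the test (adjusted p = 4.72e-06, adjusted p = 0.00882 with an estimated correlation). Skeletal muscle genes fell in 8 of 25 cases (20 adjusted over the list alone, median -0.57). Its list had adjusted p = 1.87e-07 with the preset and adjusted p = 0.345 with an estimated correlation.

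**Figure D5:**
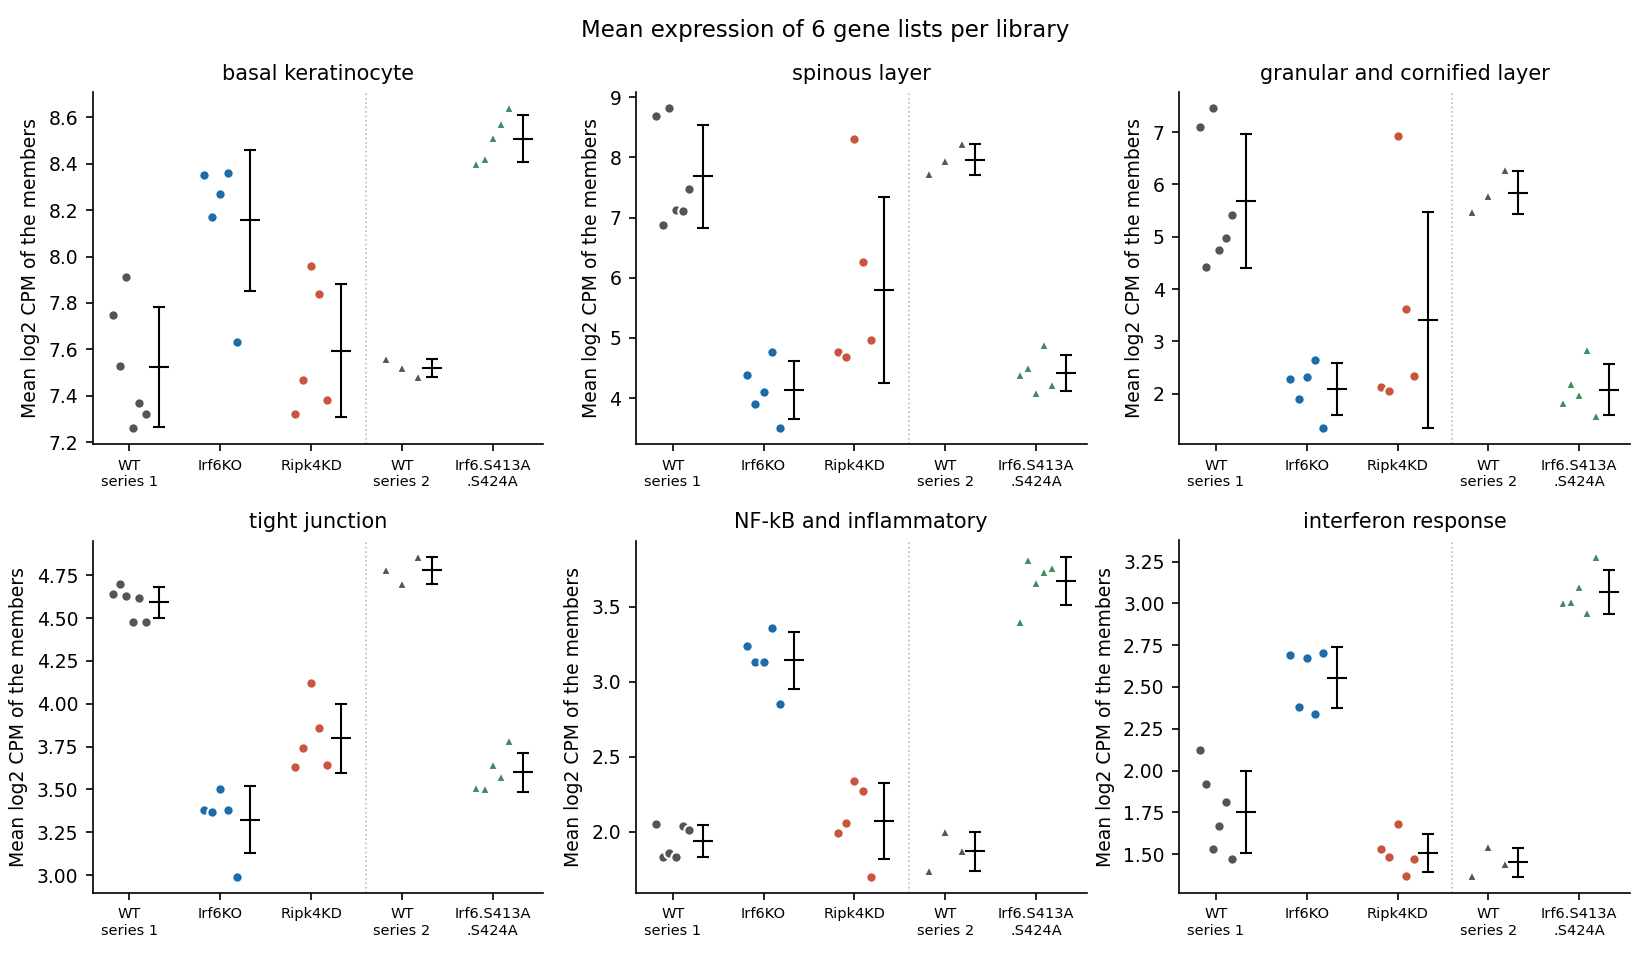
Mean log2 CPM of the members of 6 gene lists per library, with mean and SD per group and the 2 number series on either side of the dotted line. The 5 Irf6KO and 5 Irf6.S413A.S424A libraries lie above all WT libraries of their series in the interferon and NF-kB lists, and Ripk4KD replicate 3 lies among WT in the spinous and granular lists.

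Irf6KO and Ripk4KD were compared to ask where the alleles differ. Interferon and NF-kB genes were higher and periderm genes lower in Irf6KO. The largest rises were Il24 (41.4-fold, SE 0.66), Ptprn (16.4-fold, SE 0.4), the natriuretic peptide gene Nppb (16.4-fold, SE 0.33, adjusted p = 4.65e-08), Il1b (13.2-fold, SE 0.57) and the smooth muscle actin gene Actg2 (7.53-fold, SE 0.22). The largest falls were Skint2 (3 counts in Irf6KO, ratio 261, counting interval 88.9 to 1270), Acer1 (194-fold, SE 1.05), P2ry4 (0 counts, at least 34.5-fold), Cyp2b19 (96.2-fold, SE 1.39) and Ly6g6c (94.5-fold, SE 1.22). Without Ripk4KD replicate 3 the log2 changes of Acer1, Cyp2b19 and Ly6g6c were -5.50, -2.92 and -3.28, that of Il24 was 6.78, the ratio of Skint2 was 39.3 (13 to 195), and P2ry4 was at least 4.58-fold lower and lost its call (adjusted p = 0.0404 with and 0.245 without it), as it did without Irf6KO replicate 1, 2, 4 or 5 (0.0828, 0.0853, 0.0679 and 0.0672) or Irf6.S413A.S424A replicate 3 (0.074). Il1b was at log2 3.08 without Irf6KO replicate 1.

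In this comparison 1984 of 19248 genes passed, 771 higher and 1213 lower in Irf6KO, but each genotype lay in a number run of its own, and with the runs as a block the count was 53. It was also 3828 without Irf6KO replicate 3, 1163 without Irf6KO replicate 1 and 1108 without Irf6KO replicate 2. Without Ripk4KD replicate 3, WT replicate 1 and WT replicate 4 the balance turned round, with 1623 higher and 1321 lower. Il24, Il1b, Skint2, P2ry4, Cyp2b19 and Ly6g6c did not pass with the block (adjusted p = 0.731, 0.228, 0.0709, 0.683, 0.253 and 0.135). The interferon, NF-kB and periderm lists stayed past the threshold under the block, and the S100 family list, higher in Irf6KO (adjusted p = 0.0337, adjusted p = 0.516 with an estimated correlation), did not (0.112), nor did it without Ripk4KD replicate 1, 2 or 5 or Irf6KO replicate 4 (0.0774 to 0.122). Interferon genes were higher in 19 of 25 cases (21 adjusted over the list alone), with Oasl2, chosen for this comparison after its values were seen, 5.55-fold higher (SE 0.23; adjusted p = 7.7e-27, adjusted p = 0.00274 with an estimated correlation, 2.16e-20 with the block). NF-kB genes were higher in 12 of 20 (12 adjusted over the list alone; adjusted p = 5.44e-19, adjusted p = 7.73e-05 with an estimated correlation, 7.17e-19 with the block). Periderm genes were lower in 7 of 13 and Krt17 higher (7 and 1 adjusted over the list alone; adjusted p = 1.29e-12, adjusted p = 0.0148 with an estimated correlation, 1.87e-24 with the block).

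Spinous genes were lower in 10 of 17 cases (14 adjusted over the list alone; adjusted p = 8.15e-07, adjusted p = 0.397 with an estimated correlation) and granular genes in 11 of 20 (15 adjusted over the list alone). The list's adjusted p was 0.000348, and adjusted p = 0.563 with an estimated correlation. Without Ripk4KD replicate 3 the counts were 5 and 3, the granular median was -0.56 and its list did not pass (adjusted p = 0.0625). Genes of the pericyte and smooth muscle list were higher in 4 of 12 cases and lower in 1 (5 and 3 adjusted over the list alone), with a median of -0.19, opposite in sign to the test. Its adjusted p was 0.025, and adjusted p = 0.198 with an estimated correlation, and the call was lost without Irf6KO replicate 3 (0.131). Basal genes were higher in 7 of 17 cases (9 higher and 1 lower adjusted over the list alone). List adjusted p was 5.01e-08, and adjusted p = 0.167 with an estimated correlation. Skeletal muscle genes were lower in 22 of 25 (24 adjusted over the list alone). List adjusted p was 9.62e-20, and adjusted p = 0.0776 with an estimated correlation. Erythroid genes were lower (9 of 18, 14 adjusted over the list alone). So were Merkel cell genes (3 of 10, 3 adjusted over the list alone). Leukocyte genes were higher (2 of 19, 2 adjusted over the list alone). In turn adjusted p was 1.62e-07, 0.000684 and 0.000684, and adjusted p = 0.167, 0.0155 and 0.421 with an estimated correlation. Overlap of the Merkel cell and periderm lists was not tested, so fewer Merkel cells are not shown.

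Irf6.S413A.S424A was compared with Irf6KO to ask whether the knock-in differs from loss of the gene. The difference between single genes was past the threshold for Irf6 alone (5.29-fold higher, SE 0.29, adjusted p = 0.000535), whose RNA the knockout lowers and the knock-in does not. edgeR called 1 of 19248 genes, with 546 at unadjusted p under 0.05, and DESeq2 called 4: Irf6, Irf9 (log2 0.55, adjusted p = 0.0116), Parp9 (0.75, 0.0116) and Upk1b (-1.50, 0.0227), of which the last 3 were chosen after their values were seen. Without the series term edgeR called 7160 genes and Irf6 was 8.46-fold higher, but the series and these genotypes coincide except through WT. Over the 3209 genes that passed in Irf6KO against WT, the median size of the change was 0.72 log2 units in Irf6KO and 0.74 in Irf6.S413A.S424A in the same sign, with 99% in the same direction. The median standard error of the difference between the genotypes was 0.26, and in simulated counts 56.7% of genes changed 2-fold were recovered, so that moderate differences of single genes can have been missed.

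As groups, 8 of 41 lists were higher and 5 lower in Irf6.S413A.S424A than in Irf6KO, of which 3, all inflammatory or immediate early, held with an estimated correlation. The 25 interferon genes had a median log2 difference of 0.79, with 0 past the threshold over all genes and 14 higher adjusted over the list alone (adjusted p = 2.78e-31, adjusted p = 0.00199 with an estimated correlation, 0.0025 without the series term). Oasl2 and Gbp2, chosen here after their values were seen, differed by log2 1.37 (SE 0.34) and 1.35 (SE 0.38). The NF-kB list (median 0.47, 0 genes by either count, 0 adjusted over the list alone; adjusted p = 4.73e-08, adjusted p = 0.0106 with an estimated correlation) and the immediate early list (median 0.39, 0 genes over all and 4 higher adjusted over the list alone; adjusted p = 3.87e-09, adjusted p = 0.0168 with an estimated correlation) did not pass without the series term (0.0852 and 0.521). Basal keratinocyte genes were also higher (median 0.38; adjusted p = 2.09e-06, adjusted p = 0.505 with an estimated correlation, 0.0795 without the series term). Dermal fibroblast and endothelium genes were lower (medians -0.19 and -0.14; adjusted p = 4.87e-06 and 2.49e-05, adjusted p = 0.505 each with an estimated correlation, 3.71e-05 and 0.0109 with the 3 runs as a block). Melanocyte genes were lower (median -0.25; adjusted p = 0.00542, adjusted p = 0.633 with an estimated correlation), a call lost without WT replicate 5 (0.07) or Irf6KO replicate 4 (0.0913). Without the series term the direction of this list and of the periderm list was higher, and neither passed (0.883 and 0.857). The periderm list was lower by the test with a median of 0.08 (adjusted p = 0.0179, adjusted p = 0.633 with an estimated correlation), and did not pass with the 3 runs as a block (0.325), without WT replicate 2, 4, 6 or 9 (0.0507 to 0.276), without Irf6KO replicate 1, 2 or 4 (0.0568 to 0.0727) or without Irf6.S413A.S424A replicate 1 or 3 (0.06 and 0.0537). No gene of these 5 lists was past the threshold over all genes, and 1, of the periderm list, was lower adjusted over the list alone. The spinous and granular lists did not differ by the test (adjusted p = 0.933 each), but they were lower in Irf6.S413A.S424A with the embryonic globin share in the fit (0.00222 and 1.98e-05) and without Ripk4KD replicate 3, WT replicate 1 and WT replicate 4 (0.000479 and 2.66e-07). These WT replicates had the highest granular scores of WT and belong to the first series. Leaving them out lowers the WT baseline of Irf6KO alone, so that fit cannot tell whether the knock-in differs from Irf6KO.

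Irf6.S413A.S424A was compared with Ripk4KD to ask whether the knock-in resembles the Ripk4 allele. Inflammatory genes were higher and periderm genes lower in the knock-in. The largest rises were Mmp13 (192-fold, SE 1.93, adjusted p = 0.0301), Nppb (36.3-fold, SE 0.6, adjusted p = 1.58e-05), the prostaglandin synthase gene Ptgs2 (31.4-fold, SE 0.83), Ptprn (30.7-fold, SE 0.66) and the noncoding RNA Lncenc1 (25.2-fold, SE 0.66). The largest falls were Sdr9c7 (1 count, adjusted p = 0.0251), Ly6g6c (235-fold, SE 1.7), Acer1 (194-fold, SE 1.33), Krt77 (148-fold, SE 0.8, adjusted p = 9.47e-06) and Cnfn (133-fold, SE 1.82, adjusted p = 0.033). Without Ripk4KD replicate 3 the log2 changes of Ly6g6c, Acer1, Krt77 and Cnfn were -4.59, -5.50, -6.04 and -3.55. With the 3 runs as a block Mmp13, Sdr9c7 and Cnfn did not pass (adjusted p = 0.0725, 0.0786 and 0.087). Mmp13 (1 count in second-series WT) was 103-fold higher without Irf6.S413A.S424A replicate 4 and 59.7-fold without the series term. It was lost without WT replicate 2, 3, 5, 6, 8 or 9 (adjusted p 0.0508 to 0.0927), Sdr9c7 without WT replicate 9 or Irf6.S413A.S424A replicate 1, 2 or 5 (0.054 to 0.0728), and Cnfn without Ripk4KD replicate 3, WT replicate 5, 6 or 9 or any Irf6.S413A.S424A replicate (0.0518 to 0.105).

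Here 601 of 19248 genes passed, 396 higher and 205 lower in Irf6.S413A.S424A; the count was 927, 359 and 332 without WT replicates 4, 5 and 9, 301 with the 3 runs as a block and 9808 without the series term. Interferon genes were higher in 19 of 25 cases (22 adjusted over the list alone), with Oasl2, chosen here after its values were seen, 14.3-fold higher (SE 0.36). This list's adjusted p was 1.45e-50 with the preset and adjusted p = 5.84e-05 with an estimated correlation. NF-kB genes were higher in 12 of 20 (13 adjusted over the list alone; adjusted p = 4.42e-25, adjusted p = 1.57e-05 with an estimated correlation) and immediate early genes in 5 of 19 (12 adjusted over the list alone). Adjusted p for this list was 9.49e-12 with the preset and adjusted p = 0.00501 with an estimated correlation. Periderm genes were lower in 6 of 13 and Krt17 higher (6 and 1 adjusted over the list alone). Its list had adjusted p = 1.36e-16 with the preset and adjusted p = 0.00381 with an estimated correlation. Basal genes were higher in 7 of 17 cases (10 adjusted over the list alone). The list's adjusted p was 1.13e-13 with the preset and adjusted p = 0.0606 with an estimated correlation. Granular genes were lower in 3 of 20 (8 adjusted over the list alone; adjusted p = 0.000184, adjusted p = 0.503 with an estimated correlation), and without Ripk4KD replicate 3 in 0 (1 adjusted over the list alone), where the list did not pass (0.0793).

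The changes of the 3 genotypes against WT were set beside each other. Irf6KO and Irf6.S413A.S424A shared 2222 called genes in the same direction (959 higher, 1263 lower; 0 opposite), where independent lists would share 98.6 and 144.6. The fold changes correlated across genes at 0.89 (covariance 0.75), against a mean of 0 (covariance 0) in simulations of unchanged groups, and with separate WT libraries the overlap was 1396 and the correlation 0.92 (covariance 0.697). Irf6KO and Ripk4KD shared 566 (54 higher, 512 lower; 1 opposite), where independent lists would share 5.6 and 57.5. Their correlation was 0.72 (covariance 0.341) against a simulated 0.45 (covariance 0.03), since they share WT libraries of 1 series, and with separate WT libraries 45 genes were shared at a correlation of 0.72 (covariance 0.287). Ripk4KD and Irf6.S413A.S424A shared 531 (53 higher, 478 lower; 4 opposite), with 6.6 and 42.2 for independent lists, at a correlation of 0.68 (covariance 0.36; simulated 0 and 0) and 45 genes at 0.73 (covariance 0.323) with separate WT libraries. No simulation shared a called gene (highest 0 of 20 simulations). Simulated genes were drawn independently, without the joint differences of differentiation genes between real WT libraries. The simulations can therefore understate the overlap and correlation that shared WT libraries give. The overlap of Irf6KO and Ripk4KD was 1242 without Ripk4KD replicate 3, 370 without WT replicate 1, and 367 and 374 without Ripk4KD replicates 2 and 5; that of Ripk4KD and Irf6.S413A.S424A was 1066 without Ripk4KD replicate 3 and 352 without Ripk4KD replicate 2. Genes are not independent replicates in such correlations.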

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

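The 6 counts of other sample splits were set up before their results were seen, but the number of splits drawn was lowered to 70 for running time after the counts of a larger draw had been seen; all the other tests in this part were chosen after the result they address had been seen. In each of the 4 genotypes (9 libraries of WT and 5 of each other), 14 measures were searched for a library standing apart, 56 groups in all, and chance alone marks about 1 in 20 such groups. It was found 5 times. Irf6KO replicate 4 had an embryonic globin share of 0.966% (the others 4.94 to 6.18). Irf6KO replicate 5 had the lowest basal keratinocyte score (7.63 against 8.17 to 8.36), tight junction score (2.99 against 3.37 to 3.5) and log2 CPM of Ripk4 (5.68 against 6.52 to 6.7). Ripk4KD replicate 1 had the highest leukocyte score (5.17 against 4.6 to 4.74). The difference between 2 genotypes' changes against WT was past the threshold for 1984 genes between Irf6KO and Ripk4KD, 1 gene between Irf6.S413A.S424A and Irf6KO (edgeR; 546 at unadjusted p under 0.05, and 4 with DESeq2) and 601 genes between Irf6.S413A.S424A and Ripk4KD. The 1984 were 53 with the 3 runs of sample numbers as a block, 3828 without Irf6KO replicate 3, and 1163 and 1108 without Irf6KO replicates 1 and 2. The 601 were 927, 359 and 332 without WT replicates 4, 5 and 9.

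For each comparison 70 splits of its libraries into groups of the same sizes were drawn, the real one included. The real split called the most genes for Irf6KO against WT (3209 genes, highest other 2043), Irf6.S413A.S424A against WT (2934, 63) and Irf6.S413A.S424A against Ripk4KD (601, 0), with 1 split as large in each. Splits were not kept within the number series, so this count alone does not exclude chance. For Ripk4KD against WT (653) 3 splits were as large, which leaves chance open. The highest other, 2583 genes, set Ripk4KD replicates 3 and 4 with WT replicates 1, 4 and 5. A split that calls several times the real count points to a structure of the samples: Ripk4KD replicate 3 and WT replicates 1 and 4 have the lowest embryonic globin shares. For Irf6KO against Ripk4KD (1984; 3 splits) the highest other, 3619, exchanged Irf6KO replicate 3 for Ripk4KD replicate 1. For Irf6.S413A.S424A against Irf6KO the real count was 1 and the highest other 1 (3 splits as large).

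Ripk4KD replicate 3 lay nearer to WT than the others of its group in spinous and granular genes. A WT library under the wrong label was tested in 2 ways, of which the second was chosen after the first had been seen. The share of called genes in which it lay beyond every first-series WT library was 22.1%, within the 2.2 to 52.5% found for WT libraries left out in turn, and so did not separate the cases. Counting only genes at least 4-fold beyond gave 27, against 0 to 4 for the WT libraries, which argues against that label. More epidermis in the sample would raise basal and granular genes alike, but against the mean of the other 4 libraries its granular score was higher by 4.4 and its basal score by 0.46 log2 units, a gap of 3.94; an embryo further on in development may explain the pattern, as the embryonic globin share of 0.29% was the lowest of the 24 libraries.

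Between Irf6.S413A.S424A and Irf6KO, 1 gene passed with the number series in the fit and 7160 without it. The differences without the term correlated at 0.82 across genes with those between WT libraries of the 2 series, consistent with a batch that follows the number series; genes are not independent replicates here. Too low a precision through WT to call any gene is argued against by the 601 genes called against Ripk4KD. Smaller differences stay open, and larger ones too: Oasl2 and Gbp2 differed over 2-fold and were not called.

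Interferon response genes were higher in Irf6KO and Irf6.S413A.S424A than in WT, and the leukocyte score was higher too. More leukocytes are argued against as the whole cause, though a part could be theirs: the interferon score rose beyond the leukocyte score by 0.48 log2 units in Irf6KO (two-sided exact permutation p = 0.026, Benjamini-Hochberg 0.039, above all WT in 3 of 5 libraries) and by 1.22 in Irf6.S413A.S424A (p = 0.0179, the smallest this exact test can give, 0.039, 5 of 5). The labels name no sort, and abundant leukocyte genes moved apart: Mrc1 was at 82.4 ± 17.5 and 106 ± 11.7 CPM (SD) in first- and second-series WT, 86.8 ± 18.7 in Irf6KO and 93.3 ± 16.1 in Irf6.S413A.S424A, with fitted changes of log2 0.08 (SE 0.16) and -0.19 (SE 0.19), and Csf1r at 82.2 ± 12.7, 49.6 ± 4.73, 98 ± 19.6 and 71.4 ± 13.9, with log2 0.25 (SE 0.15, adjusted p = 0.27) and 0.53 (SE 0.18, adjusted p = 0.0539), whereas Cd14 rose 1.93-fold and 3.62-fold and Lyz2 1.64-fold (adjusted p = 0.0891 with the 3 runs as a block) and 2.44-fold. A batch that follows the 3 runs is argued against by the list's adjusted p of 8.12e-10 or lower in both with the runs as a block. A change of state within leukocytes or keratinocytes stays open, and a response of skin cells to the alleles is a hypothesis that was not tested further.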

How the results depend on the processing

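Direct tests of the processing used alternatives named at the start and 3 chosen after seeing the data: a sex term, the embryonic globin share as a term, and leaving out Ripk4KD replicate 3, WT replicate 1 and WT replicate 4 together. Values are compared with 3209, 653 and 2934 genes for Irf6KO, Ripk4KD and Irf6.S413A.S424A against WT, 1984 for Irf6KO against Ripk4KD, 1 and 601 for Irf6.S413A.S424A against Irf6KO and Ripk4KD, and overlaps of 566 (Irf6KO and Ripk4KD), 2222 (Irf6KO and Irf6.S413A.S424A) and 531 (Ripk4KD and Irf6.S413A.S424A). Without the series term Ripk4KD against WT gave 1211, Irf6.S413A.S424A gave 7802 against WT, 7160 against Irf6KO and 9808 against Ripk4KD, the first overlap was 873, and the correlations of Irf6.S413A.S424A with Irf6KO and Ripk4KD were 0.76 and 0.49. With the 3 runs as a block the counts were 1883 (Irf6KO against WT), 297 (Ripk4KD against WT), 53 (Irf6KO against Ripk4KD) and 301 (Irf6.S413A.S424A against Ripk4KD), with first and last overlaps of 276 and 275. With only the groups compared in the fit they were 349 (Ripk4KD against WT) and 1013 (Irf6KO against Ripk4KD), with overlaps of 319 and 311, where fewer libraries inform the spread. With no filter on low counts the 3 correlations were 0.57, 0.49 and 0.3. DESeq2 called 4 genes between Irf6.S413A.S424A and Irf6KO. Separate WT libraries per genotype gave overlaps of 45, 1396 and 45, with fewer WT libraries in each contrast. With the globin share in the fit Ripk4KD against WT gave 1139 and Irf6.S413A.S424A against Ripk4KD 1099, with overlaps of 856 and 894, and without the 3 libraries 1153, 977, 859 and 924. With an estimated correlation 6, 4 and 7 of the 41 lists passed in Irf6KO, Ripk4KD and Irf6.S413A.S424A against WT, in place of 23, 18 and 21. Except where fewer libraries are named, the cause was not tested.

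Leaving out 1 library at a time gave 2445 to 3757 genes for Irf6KO against WT, 399 (without Ripk4KD replicate 2) to 1739 (without Ripk4KD replicate 3) for Ripk4KD, 1872 (without WT replicate 9) to 3282 for Irf6.S413A.S424A, 1108 (without Irf6KO replicate 2) to 3828 (without Irf6KO replicate 3) for Irf6KO against Ripk4KD, 1 to 1 for Irf6.S413A.S424A against Irf6KO and 332 (without WT replicate 9) to 927 (without WT replicate 4) against Ripk4KD. Beyond 1.5 times also lay Ripk4KD against WT without WT replicate 1 (404) and Ripk4KD replicates 1 and 5 (426 and 406), Irf6KO against Ripk4KD without Irf6KO replicate 1 (1163), and Irf6.S413A.S424A against Ripk4KD without WT replicate 5 (359). Overlaps were 367 to 1242 (370 without WT replicate 1, 374 without Ripk4KD replicate 5), 1569 to 2504 and 352 to 1066, the ends of the first and last without Ripk4KD replicates 2 and 3. Correlations were 0.64 to 0.78, 0.84 to 0.9 and 0.62 to 0.7, and the lists passing 22 to 25, 15 to 21 and 19 to 23. Of 10326 values of named genes over all alternatives, 9961 kept direction and side of the threshold, 358 fell short of it, 6 newly passed and 1 reversed: Jag2 in Irf6.S413A.S424A against WT at -0.17 without the series term (adjusted p = 0.38). Fitted folds of named genes moved by over 1.5 times in both directions: with the sex term 5 rises were smaller and 8 falls larger, with the globin share 9 rises were larger, 3 smaller and 25 falls smaller, without the 3 libraries 6 rises were larger, 3 smaller, 3 falls larger and 28 smaller, and 7 values moved without the series term and 7 with the 3 runs as a block. No paired analysis was possible, as the labels name no litters. Depth limits genes at 0 or few counts, given as bounds or counting intervals.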

Other observations

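The test of this part was chosen after the result it addresses had been seen. WT libraries labelled with the same embryonic day differed in differentiation: the granular score ran from 4.42 to 7.46 log2 CPM. A candidate explanation is that embryos differed in developmental progress, which the embryonic globin share, from blood rather than epidermis, could measure apart from keratinocyte genes. Over the 9 WT libraries the log2 share correlated with the granular score at r = -0.87 (two-sided exact permutation p = 0.00327, Benjamini-Hochberg 0.00436 over 4 measures; rho -0.88, p = 0.00308). Within the 6 WT libraries of the first series r was -0.91 (exact permutation p = 0.0347, adjusted 0.0463; rho -0.77, p = 0.103), and the second series held 3 libraries, too few for a value. Without the 2 libraries farthest from the median share, WT replicates 1 and 4, r was -0.51 (exact permutation p = 0.23; rho -0.75, p = 0.0663), and for the spinous score r was -0.63 (p = 0.125; rho -0.79, p = 0.048). Of the other measures over all 9, spinous and basal scores gave r = -0.88 each (exact permutation p = 0.00163 and 0.00316) and skeletal muscle 0.58 (p = 0.103). Without WT replicates 1 and 4 basal r was -0.55 (exact permutation p = 0.216; rho -0.57, p = 0.2) and skeletal muscle r 0.24 (rho 0.07), so that the relation rests on those libraries, except for the rank order of the spinous score.

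With the share as a term beside genotype, 4533 genes varied with it (1716 rising, 2817 falling). All 20 granular and cornified layer genes fell as it rose. The fit was not repeated without Ripk4KD replicate 3 and WT replicates 1 and 4, lowest in share and highest in granular score. Irf6KO replicate 4 (0.966%) had a granular score of 2.64, below all WT, and Ripk4KD replicate 3 (0.29%) one inside the WT range.

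Levels of 2 smooth muscle genes differed between the genotypes. Tagln stood at 23.9 ± 3.08 CPM (SD) in WT, 325 ± 125 in Irf6KO, 50.1 ± 13.1 in Ripk4KD and 621 ± 217 in Irf6.S413A.S424A, and Actg2, chosen after its values were seen, at 2.71 ± 0.404, 59.4 ± 19.5, 7.87 ± 1.19 and 129 ± 46.5. Which cells carried these transcripts was not measured.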
